A study of Arabidopsis thaliana with 2 samples.

How the data were processed

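Data from 2 samples were used, labelled replicate 1 with iron and replicate 1 without iron. Per the labels' protocols, 3 biological replicates were made per reporter line, and the other replicates were not used here. Per the labels' protocols, roots were transferred for 24 h, protoplasted and sorted by fluorescence, total RNA was extracted with a micro-scale column kit, and biotin-labelled cRNA was made with Affymetrix's amplification in successive rounds and read on a 1-colour array. Amplification in rounds from few cells favours the 3' ends of transcripts and can widen differences between arrays, and protoplasting itself changes some transcripts in both conditions.

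The deposited values are intensity per probe set, 1 column per sample, with background correction, summarisation, normalization and scaling not given in the sources used here. They lie on a linear scale, as all are above 0 and right-skewed and the hybridisation controls span a wide range, and the scaling that brings both medians near 0.86 stays unknown. Whether a column is a single array or a summary of several is not stated beyond its replicate number, and each is taken here as 1 array. The median was 0.852 with iron and 0.866 without, and the SD of the log2 values was 0.983 and 1.31. The authors also deposited a q-value per probe set for the difference between the conditions, per the labels. The test, the arrays behind it and the way q was estimated are not given in the sources used here, so q values are quoted only as those of the authors' deposited table. No per-sample column was left unused.

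The table held 22801 probe sets, of which 55 were Affymetrix controls, leaving 22746 plant probe sets. Gene names came from the platform's probe table, which can be dated, updated by gene ID through a reference gene table of assembly TAIR10.1, whose coordinates were not used. It paired 13513 probe sets with 1 gene (13356 genes), 503 with several genes and 8785 with none. Of the 13513, 13436 were found by gene ID and 77 kept the platform's name. Probe sets with several genes or none were counted but never named. As a result, 52 of the 298 genes in the 20 fixed lists had a single-gene probe set, and genes without one were not analysed here. For 15 genes with more than 1 probe set past the filter, the pooled SD of the log2 difference between probe sets of a gene was 0.33, and their mean was used.

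The difference of a probe set is log2 of the value without iron minus log2 of the value with iron. The planned pseudocount of 16 assumed intensities far above it. Because the deposited intensities have medians under 1, the main values use no pseudocount, a choice made after seeing the data, and 16, 1 and 64 were run as alternatives. A probe set passed the expression filter when the higher of its values was at or above the median of all plant values, 0.858. Counts used fixed sizes, 2-fold, or 1.5-fold together with q under 0.05 in the authors' deposited table. Values relative to like brightness are differences minus a lowess curve (fraction 0.2) of difference on mean log2 value over all plant probe sets. Their local SD is a robust SD over 500 probe sets of like brightness. The authors' q values were not computed for these relative values, also where both are printed together.

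The median of each gene list with at least 3 genes past the filter was placed among 10000 random lists of the same size, matched on mean value in 20 bins. This percentile describes these arrays and is not a p-value across replicates. Lists covered iron regulators, iron acquisition, iron transport and chelation, iron storage and iron-requiring enzymes, iron-sulfur clusters, other metals, tetrapyrroles, phenylpropanoids, lateral root initiation, auxin, the cell cycle, ethylene and stress, plus 7 lists of root cell type markers. Named genes followed a rule with 3 parts. They were members of the iron regulator, acquisition and transport lists and FER1 to FER4 with q under 0.05 in the authors' deposited table or a 2-fold difference (up to 25), the 10 highest and 10 lowest genes with q under 0.05 in the authors' deposited table, and up to 4 members of each other list past the filter by size of difference, plus the brightest member of each cell type list. The lists, the naming rule, the filter and, except where stated, the alternatives listed next were fixed before the data were examined.

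Alternatives were quantile normalization of the pair, the median difference set to 0, subtraction of the lowess curve, no filter or a filter at the 75th percentile (1.66), probe sets ending in _s_at or _x_at left out, pseudocounts, other fold and q thresholds, the brightest probe set per gene, and the mean over a list. The median difference set to 0 was that of the probe sets past the filter. Removal of an offset and a scale factor fitted over all plant probe sets was added after seeing the data. The procedure was tested on 1 simulated pair of arrays with 22746 probe sets, built from the lowess trend and local SD of these arrays with normal noise. The same lowess fit then removed the trend, so recovery was favoured by construction and says nothing about replicate error. Changes of +1, -1, +2 and -2 on the log2 scale, 50 probe sets each, were found at 1.5-fold after trend removal in 100%, 96.0%, 100% and 100% of cases, against 52.0% for -1 without trend removal. Of unchanged probe sets past the filter, 0.34% exceeded 1.5-fold after trend removal and 23.6% without it. A planted list of 7 genes, each raised by 1 on the log2 scale, reached the 100th percentile, and 3.0% of 200 unplanted lists of 7 lay in the lowest or highest 2.5% of random lists. The unplanted lists were drawn at random from the same probe sets as the random lists, so a low rate was favoured by construction. Smaller lists, smaller shifts of a list and lists whose genes vary together were not simulated. For arrays, their number limits the precision, and with 1 per condition no replicate error can be given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.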

Results

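Pericycle cells, the outermost cell layer of the root's vascular cylinder and the layer in which lateral roots begin, were sorted from Arabidopsis thaliana seedling roots (ecotype Columbia) by the green fluorescence of the reporter line J2661. Seedlings grew for 6 days on standard medium and were then kept for 24 h on medium with iron, or on medium whose iron was replaced by 0.3 mM ferrozine, an iron chelator, and were 7 days old when the roots were protoplasted. Biotin-labelled cRNA, amplified in successive rounds from total RNA of the sorted cells, was hybridised to Affymetrix arrays. From these, 1 column of values per condition, labelled replicate 1 and taken here as 1 array, was analysed. The comparison asks how pericycle cells respond to 24 h without iron. With 1 array per condition no difference has a replicate check, so "higher" and "lower" describe this pair of arrays only, no p-value was computed, and percentiles of gene lists among random lists are descriptions of these arrays. On the array with iron, the 22746 plant probe sets ranged from 0.484 to 62.8 arbitrary linear units with a median of 0.852. On the array without iron they ranged from 0.329 to 83.5 with a median of 0.866.

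Without iron, AT5G05250, a gene of unknown function, read 4.62 against 1.19 with iron, a log2 difference of 1.96 and the largest among the named genes. The iron regulators ILR3, URI and PYE were 1.61-fold, 1.61-fold and 1.51-fold higher without iron as deposited, but 1.05-fold, 1.19-fold and 1.21-fold higher relative to probe sets of like brightness. A related regulator, bHLH115, was 0.28 higher on the log2 scale as deposited and at -0.32 relative to like brightness. The iron transporter-like gene VTL3 read 1.35 without iron and 1.82 with iron, a log2 difference of -0.44 as deposited and -0.82 relative to like brightness. EIN3, a transcription factor of the ethylene pathway, read 5.74 against 2.81, 2.04-fold higher as deposited and 1.34-fold relative to like brightness. Over all plant probe sets 11345 were higher and 11401 lower without iron, with dim probe sets mostly lower and bright ones mostly higher, so many differences below are also given relative to probe sets of like brightness.

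Of the 11872 plant probe sets past the expression filter, 10672 were higher and 1200 lower without iron, with a median log2 difference of 0.37. At least 2-fold differences were seen at 246 probe sets higher and 4 lower without iron, and at none with the planned pseudocount of 16, which exceeds most values. After the trend with brightness was subtracted, 13 probe sets were at least 2-fold higher and 29 at least 2-fold lower. Quantile normalization gave 15 higher and 27 lower, setting the median difference to 0 gave 30 and 27, and removing an offset and a scale factor gave 7 and 21. The binned median difference ran from -0.44 among the dimmest of 20 brightness bins to 0.63 among the second-brightest. Control probe sets moved in the same way: the 27 Bacillus controls, all near the lower end of the scale, were all lower without iron (median -0.42), and the 9 hybridisation controls were all higher (median 0.36). The log2 ratio of 3' to 5' control probe sets differed between the arrays by -0.63 to 0.38 across 6 transcript sets. Pearson's r of the log2 values was 0.978 and Spearman's rho 0.983 across probe sets, which are not independent replicates.

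**Figure D1:**
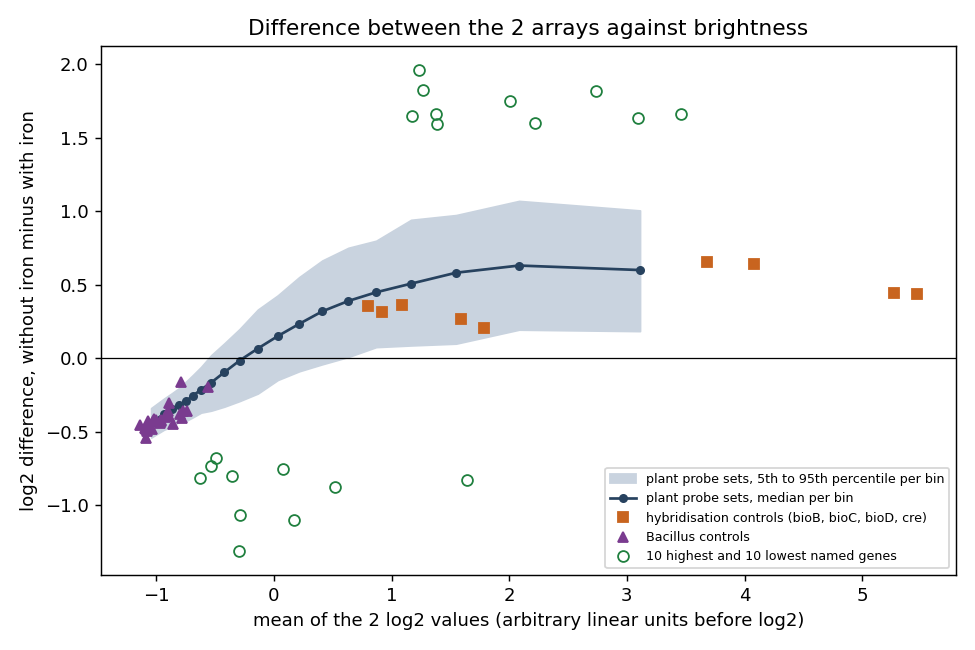
Log2 difference between the arrays (without iron minus with iron) against the mean of both log2 values, in arbitrary linear units before log2, for 22746 plant probe sets. The line joins the medians of 20 brightness bins and the band spans the 5th to 95th percentile of each bin. Triangles are 27 Bacillus control probe sets, squares 9 hybridisation control probe sets, and open circles the 10 highest and 10 lowest named genes. The median climbs from -0.44 in the dimmest bin to 0.63 in the second-brightest, the triangles lie below 0 and the squares above 0.

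In the authors' deposited table, 5283 of the 11872 probe sets past the filter had a q value under 0.05, and 5029 of these were higher and 254 lower without iron. With a difference of at least 1.5-fold between the arrays required as well, 2556 probe sets were higher and 22 lower, or 99.1% higher. Direction and size in these counts come from this pair of arrays, and only q comes from the authors' deposited table. With the same q values of the authors' deposited table but differences taken relative to probe sets of like brightness, 113 were higher and 32 lower (77.9% higher). This share follows a selection by q in the authors' deposited table that by itself held 95.2% higher. Without q, the relative differences at 2-fold were 31.0% higher, but that share also differs in its fold threshold, so the effect of q alone was not separated. All 113 were among the 2556, and 16 of the 32 were among the 22. The trend subtracted was positive for most probe sets past the filter, so the first overlap was largely fixed by the subtraction. The split under the q values of the authors' deposited table was 114 to 40 after quantile normalization (74.0% higher), 323 to 150 with the median difference set to 0 (68.3%), and 80 to 21 with an offset and a scale factor removed (79.2%). Below the filter, 8667 of 10874 probe sets had a q value under 0.05 in the authors' deposited table, 8623 of them lower without iron. All 27 Bacillus controls also had a q value under 0.05 in the authors' deposited table.

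The 10 genes with the largest positive difference among single-gene probe sets with q under 0.05 in the authors' deposited table were 3.03-fold to 3.89-fold higher without iron. AT5G05250 remained 2.72-fold higher relative to probe sets of like brightness. Its q in the authors' deposited table, not computed for this relative value, was 1.99e-07. AT3G53960, a gene of the NPF family of nitrate and peptide transporters, read 1.28 with iron and 4.54 without, log2 differences of 1.83 as deposited and 1.30 relative to like brightness. AT3G57020, a strictosidine synthase-like gene, read 3.55 and 12.5 (1.82 and 1.20), and AT1G50060, which encodes a secreted protein of the PR-1 superfamily, read 2.19 and 7.39 (1.75 and 1.15). AT5G54370, AT3G19430 and AT4G27400, all related to late embryogenesis abundant proteins, had log2 differences of 1.66, 1.66 and 1.65 as deposited and 1.06, 1.12 and 1.15 relative to like brightness. AT3G10020, a gene also known for its induction by low oxygen, read 4.84 with iron and 15.1 without (1.64 and 1.02), and its q in the authors' deposited table was 8.03e-06. AT3G17110, which the reference annotation lists as a transcribed pseudogene, and CML37, a calmodulin-like calcium sensor, were 1.60 and 1.60 higher on the log2 scale as deposited, and 0.99 and 1.05 higher relative to like brightness. The robust SD among 500 probe sets of like brightness was 0.21 to 0.25 around these genes, a spread between genes and not between replicates.

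The 10 genes with the largest negative difference under the same rule had log2 differences of -0.67 to -1.31. AT1G73780, of the lipid-transfer protein superfamily, read 1.28 with iron and 0.518 without, a difference of -1.31 as deposited and -1.29 relative to like brightness. AT2G07721 read 1.65 and 0.769 (-1.10 and -1.32), and AT5G19890, a class III peroxidase, read 1.18 and 0.565 (-1.06 and -1.05, with q 1.30e-06 in the authors' deposited table). UBC29, a ubiquitin-conjugating enzyme, had a difference of -0.87 as deposited and -1.22 relative to like brightness. UCL1, an F-box protein gene, read 4.15 with iron and 2.34 without (-0.83 and -1.40), and was the brightest of the 10. AT5G67390, AT2G46380, AT3G42800, AT1G22330 and AT4G04380 had differences of -0.81, -0.80, -0.73, -0.67 and -0.76 as deposited and -0.59, -0.75, -0.57, -0.53 and -0.93 relative to like brightness, and AT4G04380 is a pseudogene in the reference annotation whose probe set can bind related transcripts. Of these 10, AT1G73780, AT5G19890, AT5G67390, AT2G46380, AT3G42800 and AT1G22330 read below the filter value of 0.858 without iron, as did AT2G07721 and AT4G04380, so the size of their differences depends on the background level.

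**Figure D2:**
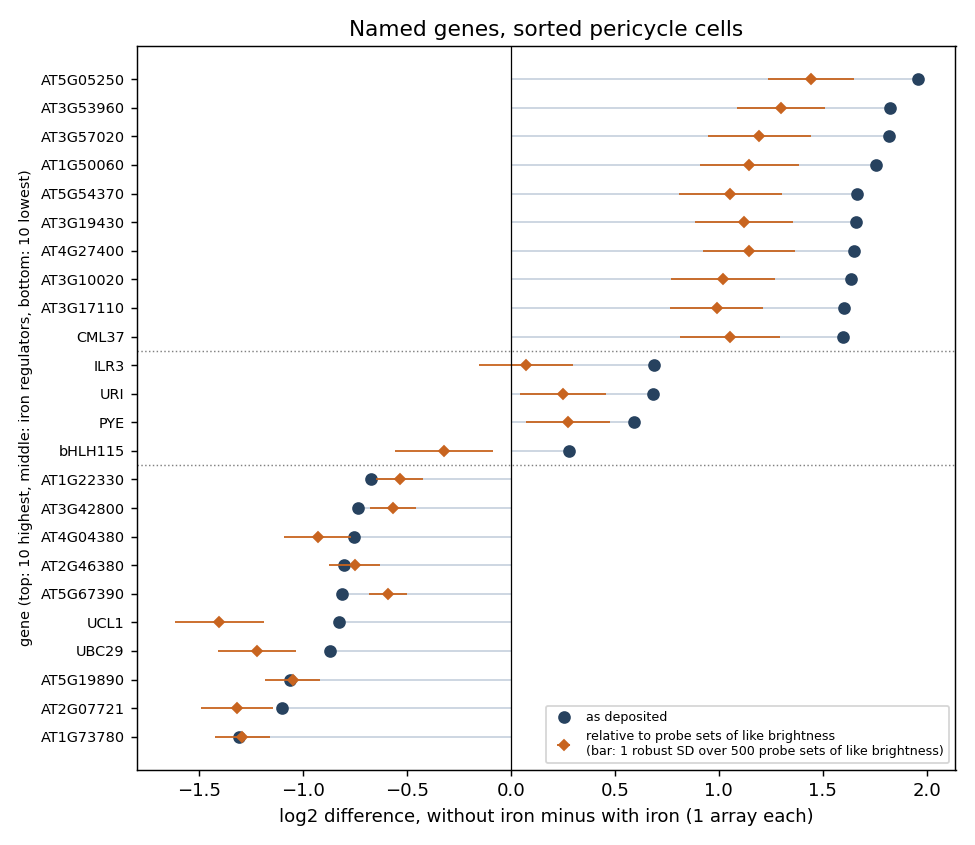
Log2 difference, without iron minus with iron, of 24 named genes from 1 array per condition. Filled circles are values as deposited, diamonds are values relative to probe sets of like brightness, and bars show 1 robust SD among 500 probe sets of like brightness. The top group holds the 10 highest genes (1.60 to 1.96 as deposited), the middle group 4 iron regulators (0.28 to 0.69, with bHLH115 at -0.32 relative to like brightness), and the bottom group the 10 lowest genes (-1.31 to -0.67).

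Of the 20 listed iron regulators, 10 were named on the array and 7 passed the filter, and 3 of these were at least 1.5-fold higher without iron. ILR3, a bHLH transcription factor that regulates iron deficiency genes, read 4.19 with iron and 6.76 without (log2 difference 0.69, 0.07 relative to like brightness). URI, the bHLH protein also called bHLH121, read 1.40 and 2.24 (0.69 and 0.25), with a q of 5.43e-11 in the authors' deposited table. PYE, a bHLH regulator of iron homeostasis first described in the pericycle, read 1.09 and 1.65 (0.59 and 0.28), with a q of 0.00161 in the authors' deposited table. bHLH115 read 3.35 and 4.07, a difference of 0.28 as deposited that became -0.32 relative to like brightness. None of the 7 was 1.5-fold higher or lower relative to like brightness, where 4 lay above and 3 below 0. The list's median difference was 0.47, at percentile 68.0 among 10000 random lists of the same size and brightness, and 0.07 relative to like brightness, at percentile 74.9. The authors' deposited table gave q under 0.05 for 4 of the 7. bHLH101, BTSL1 and the iron peptide gene IMA1 were below the filter on both arrays. Iron genes became known as iron-responsive partly from root studies that may include these arrays, so their direction is not independent evidence.

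Of the 16 genes for iron acquisition at the root surface, 5 were named and 3 passed the filter, with a median difference of 0.14 at percentile 36.2 (-0.02 relative to like brightness, percentile 45.0). None of the 3 differed by 1.5-fold or had a q under 0.05 in the authors' deposited table. S8H, an enzyme of coumarin synthesis, and the cytochrome P450 gene CYP71B5 were below the filter. None of the 17 genes for iron transport and chelation inside the root, and none of the ferritins FER1 to FER4, had a single-gene probe set named here, so these were not analysed here. Among iron storage genes and iron-requiring enzymes, 3 of 18 were named and 2 passed the filter. VTL3, a vacuolar iron transporter-like gene, had a difference of -0.44 as deposited, with a q of 0.0244 in the authors' deposited table. Relative to like brightness, for which q was not computed, VTL3 was at -0.82 (local SD 0.21). SAPX, a plastid ascorbate peroxidase, was 0.42 higher as deposited and -0.12 relative to like brightness, and VTL4 was below the filter.

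The 3 measured genes of iron-sulfur cluster assembly, out of 23 listed, had a median difference of 0.35 at percentile 53.6 and -0.01 relative to like brightness at percentile 42.3. ISU1, the mitochondrial scaffold protein, read 1.61 with iron and 2.19 without (0.45 as deposited, -0.01 relative to like brightness). NFS2, the plastid cysteine desulfurase, and HCF101, a plastid cluster carrier, had differences of 0.35 and 0.16 as deposited and -0.04 and 0.07 relative to like brightness. Of 21 genes of zinc, copper and manganese homeostasis, 3 were named and CCS1, the copper chaperone of superoxide dismutase, passed the filter at 0.62 as deposited and 0.02 relative to like brightness. GSA1, of tetrapyrrole synthesis, was 1 of 2 named genes of 11 listed and read 1.81 with iron and 1.85 without (0.03 and -0.42). HCT, a lignin pathway enzyme and the only named gene of 15 listed, read 18.3 and 26.6, a difference of 0.54 as deposited and -0.04 relative to like brightness.

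Of 12 listed auxin response genes, 4 were named and 3 passed the filter: GH3.3 and GH3.5, which encode auxin-conjugating enzymes, had differences of -0.49 and -0.14 as deposited and -0.44 and -0.38 relative to like brightness, and IAA29 had -0.22 and -0.21. Their median of -0.22 was at percentile 3.92 among random lists, and relative to like brightness it was -0.38 at percentile 0.46. None of the 3 reached 1.5-fold or a q under 0.05 in the authors' deposited table. GH3.3 and IAA29 read 0.931 and 0.885 with iron and 0.664 and 0.757 without, so both were close to the filter value and passed it only through the array with iron. The root hair markers EXPA7 and EXPA18 were also lower, with differences of -0.38 and -0.31. LBD16 and PUCHI, transcription factors of lateral root formation, were the 2 of 12 listed genes past the filter, and were 0.50 and 0.41 higher as deposited and 0.04 and 0.02 higher relative to like brightness.

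The cell cycle genes named here, 3 of 24 listed, had a median difference of 0.41 at percentile 72.5, and -0.10 relative to like brightness at percentile 28.6. The kinase AUR1 and the replication factor MCM7 were 0.45 and 0.41 higher as deposited and at -0.10 and 0.07 relative to like brightness, and the kinase AUR2 was at -0.31 and -0.26. EIN3, 1 of 2 measured ethylene genes out of 14 listed, was 2.04-fold higher as deposited, with a q of 7.06e-06 in the authors' deposited table. Relative to like brightness, for which q was not computed, EIN3 was 1.34-fold higher (log2 0.43, local SD 0.24). RTE1, a regulator of the ethylene receptor ETR1, was 0.52 higher as deposited and -0.06 relative to like brightness. None of the 15 genes of heat, wound and protoplasting stress was named here.

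Markers of other root cell types gave few values. The 2 named root hair and epidermis markers out of 13, the expansins EXPA7 and EXPA18, read 1.06 and 0.993 with iron and 0.820 and 0.802 without, and lay -0.47 and -0.36 from probe sets of like brightness. All 5 cortex markers were named and were below the filter on both arrays. SGN3, an endodermal receptor kinase and 1 of 2 named of 19 endodermis and suberin markers, read 1.46 and 1.44, a difference of -0.02 as deposited and -0.37 relative to like brightness. OPS, 1 of 2 named of 13 phloem markers, was 0.17 higher as deposited and 0.19 relative to like brightness. The only named root cap and stem cell niche marker of 8, AGL42, was below the filter. None of the 9 pericycle and stele markers or the 13 xylem markers was named here, so enrichment of pericycle transcripts was not analysed here.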

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

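All 4 tests in this part were chosen after the results they bear on had been seen. The 9 hybridisation control probe sets (bioB, bioC, bioD and cre), which carry no plant transcript and enter no count of plant probe sets, drew attention because they differed between the arrays: they were higher without iron at all 9, with a median log2 difference of 0.36 and a range of 0.21 to 0.65.

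Bright probe sets were higher and dim probe sets lower on the array without iron. A change of plant transcripts alone, with 1 common scaling factor per array, would move all controls the same way. The Bacillus controls, for transcripts no plant makes, had a median difference of -0.423 and were lower at all 27. The 9 hybridisation controls were all higher (median 0.36), and these opposite directions argue against that explanation. The Bacillus controls read at the floor, and a scaling that depends on brightness is not excluded, as the scaling is not stated. A difference in background and scale between the arrays is a candidate explanation: an offset of 0.340 units and a scale factor of 0.582, fitted over all plant probe sets, left 15.029% of the span of the binned medians, while a power law with as many parameters left 57.4%. Whether that difference arose in amplification, scanning or the unstated scaling was not tested. The hybridisation controls, left out of the fit, lay from -0.38 to 0.05 from plant probe sets of like brightness, with a median of -0.11. The brightest, cre, were on average 0.44 higher without iron, bioD 0.65, bioB 0.35 and bioC 0.24. The fitted scale factor alone gives 0.78 for bright probe sets, above the 0.44 of cre, so the controls followed the fit only in part. For the dimmer bioB and bioC the fitted offset lowers that value, so 0.78 does not apply to them. Plant probe sets in the brightest of 20 bins also lay off the fit, with a median of -0.10 after its removal. A response of single genes to iron on top of the trend stays open, as untested with 1 array per condition.

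The authors' deposited table gave q under 0.05 for 79.7% of the plant probe sets below the filter, 8623 of 8667 lower without iron. A fall of dim plant transcripts alone is argued against for the dimmest probe sets. The Bacillus controls lay at the level of plant probe sets of the same brightness, with a median of -0.031 relative to them. These controls read a median of 0.595 with iron, against 0.662 for plant probe sets below the filter, so brighter ones are not covered. Of the 27 Bacillus controls, 100.0% had q under 0.05 in the authors' deposited table, so the q values may carry the array-wide difference in background and scale. Whether the replicates not used here share that difference was not tested.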

How the results depend on the processing

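No paired analysis was possible because the conditions share only replicate number 1, and with 1 array per condition no replicate could be left out. Removal of an offset and a scale factor, and the main setting of no pseudocount in place of the planned 16, were chosen after seeing the data, and the other settings before. The median difference past the filter was 0.37 as deposited, 0.01 after quantile normalization and lowess, and closer to 0 after centring and offset removal, and the cause of the shifts below was not tested beyond that. Probe sets at least 2-fold higher and lower, 246 and 4 as deposited, numbered 15 and 27 after quantile normalization, 30 and 27 after centring, 13 and 29 after lowess, 7 and 21 after offset removal, 68 and 0 with a pseudocount of 1, and 0 and 0 with 16 or 64. They numbered 2858 and 35 at 1.5-fold and 14 and 0 at 3-fold, and the lower count was 1 with the filter at the 75th percentile. With q under 0.05 in the authors' deposited table and 1.5-fold, 2556 and 22 became 114 and 40 (quantile), 323 and 150 (centring), 113 and 32 (lowess), 80 and 21 (offset), 1163 and 3, 5 and 0, and 0 and 0 (pseudocounts 1, 16 and 64). The same counts, with q from the authors' deposited table and direction and fold from the arrays, were 798 and 5 at q under 0.001 and 302 and 2 at 0.0001. They were 233 and 4 at 2-fold, and 5029 and 254 by q alone. The lower count was 39 with no filter and 5 with the filter at the 75th percentile. The large pseudocounts exceed nearly all values and shrink every difference by construction. The median of the iron regulators, 0.47, was 0.041 (quantile), 0.11 (centring), 0.072 (lowess), 0.030 (offset), 0.35 (no filter), and 0.34, 0.052 and 0.015 (pseudocounts 1, 16 and 64), so it stayed above 0. The acquisition list, 0.14, went to -0.027, -0.23, -0.023 and -0.0064 under quantile, centring, lowess and offset, and -0.041 with no filter. The iron-sulfur list, 0.35, went to -0.0075, -0.014, -0.0051 and 0.0080 in that order, and to 0.032 and 0.0086 with pseudocounts 16 and 64. The auxin list, -0.22, was -0.39, -0.59 and -0.38 under quantile, centring and lowess and -0.011 and -0.0028 with pseudocounts 16 and 64, so it stayed below 0. The cell cycle list, 0.41, went to -0.095, 0.047, -0.097 and -0.081 under quantile, centring, lowess and offset, to 0.034 and 0.0090 with pseudocounts 16 and 64, and to 0.18 as a mean. With the filter at the 75th percentile, the acquisition, iron-sulfur, auxin and cell cycle lists kept fewer than 3 genes and gave no value. Among named genes, bHLH115 turned to -0.33, -0.088, -0.32 and -0.31 under quantile, centring, lowess and offset, and NFS2 to -0.048, -0.014, -0.042 and -0.024. Under quantile, lowess and offset, SAPX turned to -0.11, -0.12 and -0.099, HCT to -0.028, -0.043 and -0.21, and AUR1 to -0.095, -0.097 and -0.081, while HCF101 turned to -0.21 under centring. The other named genes past the filter with q under 0.05 in the authors' deposited table kept their sign under all settings that kept them. Below the filter, CYP71B5, IMA1 and S8H changed sign under lowess and offset. Of named genes without such a q, ISU1, GSA1, RTE1 and OPS changed sign under at least 1 setting. With signal near background, the size of differences among dim genes depends on the background level, and an offset between the arrays remains a candidate explanation only.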

Other observations

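The gene groups in this part were picked out after seeing the data, by symbol prefix or by location on the plastid genome, and the comparison of root hair genes with random lists is the only one here set down before its result was seen. Of 29 such groups with at least 5 genes past the filter, 4 lay in the lowest or highest 2.5% of random lists of like size and brightness. Chance alone would give 1.5 if the genes of a group varied independently, which was not tested. The 12 measured serine carboxypeptidase-like genes had a median difference of 0.57 as deposited and 0.21 relative to like brightness (percentile 99.9), with 9 above and 3 below, and a median of 0.17 to 0.21 under the 4 other scalings. In this group scpl31 and scpl50 lay 0.65 and 0.63 above genes of like brightness, and scpl35 lay at -0.41. Tau class glutathione S-transferases, enzymes of detoxification, had a median of 0.01 as deposited, -0.35 to -0.19 under the 4 other scalings, and -0.22 relative to like brightness over 7 genes (percentile 0.735), from -0.61 for GSTU27 and GSTU26 to 0.46 for GSTU18.

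The 67 plastid-encoded genes had a median difference of 0.42 as deposited. It was 0.06 with the median over probe sets past the filter set to 0. Relative to like brightness it was -0.12, after quantile normalization -0.12, and -0.14 with an offset and a scale factor removed. The direction of these genes thus turns with the scaling. Relative to like brightness, 46 of the 67 were lower and 21 higher, 9 were at least 1.5-fold lower, and none of 10000 random lists had a lower median. The random lists draw genes independently, while genes of the plastid genome may vary together, so this placement can look too extreme. The lowest were rpl16 at -1.28, petN at -1.15 and ndhG at -1.15, and the highest were psbJ at 0.56, rpl22 at 0.50 and psbA at 0.49. No explanation of this pattern was tested.

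The 5 measured alpha-expansins, which loosen cell walls, had a median of -0.31 as deposited and -0.36 relative to like brightness (percentile 0.04), and -0.67 to -0.30 under the 4 other scalings. As deposited, EXPA15, EXPA7 and EXPA18 were lower (-0.48, -0.38 and -0.31) and EXPA20 and EXPA4 higher (0.28 and 0.11), and 1 of the 5 was at least 1.5-fold lower relative to like brightness. Relative to like brightness, EXPA15 lay at -0.79, EXPA7 at -0.47, EXPA18 at -0.36, EXPA20 at -0.02 and EXPA4 at 0.08. Because EXPA7 and EXPA18 are root hair genes, the hypothesis was that fewer root hair cells were among the sorted cells of the array without iron, although the sort for the reporter should remove them. It was tested on a list of 33 root hair genes without expansins, taken from general knowledge before their values were seen, after a first choice of genes by name had matched none on the array. Of the 33, 9 were named and 5 passed the filter (AT5G04960, AT3G49960, AT4G33730, AT4G26010 and GH9C1). All 5 lay below genes of like brightness with a median of -0.27 at percentile 0.875, as the hypothesis predicted. The random lists draw genes independently, while root hair genes or expansins may vary together, so both placements can look too extreme. AT3G49960, AT4G33730 and GH9C1 read 0.87, 1.15 and 0.92 with iron and 0.70, 0.81 and 0.77 without, so they passed the filter only through the array with iron. Below the filter, AT2G47540, AT5G61550, AT3G54580 and AT3G07070 lay at -0.02, -0.01, 0.06 and -0.27 relative to like brightness. The evidence is thin: the 5 genes past the filter are few, and only AT3G49960, AT4G33730 and GH9C1 were lower as deposited. The brightest, AT4G26010, read 1.87 with iron and 1.95 without, and none of the 5 had q under 0.05 in the authors' deposited table. An effect of iron on these genes within the sorted cells stays open as untested.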
